A study of Homo sapiens with 12 samples.

How the data were processed

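Expression was measured by RNA sequencing of poly(A) RNA from U87 glioblastoma cells after 72 h with vehicle, compound 1 at 30 µM, compound 4 at 10 µM or compound 5 at 5 µM, in 3 libraries per group and 12 in all. The labels call the libraries independent biological replicates. Per the submitters' processing notes, reads were aligned to GRCh38 with STAR 2.7.10a and gene counts were processed with DESeq2 1.30.1. The deposited table holds regularized log values, which the authors made from the counts with DESeq2, on the log2 scale. The tool used for counting, the annotation release, the strand setting and any filter are not given in the sources used here. Of the genes in the table, 25759 stood at 0 in every library and 36998 varied. Depth per library is unknown, since no counts were given, and no counting interval was computed; precision was taken from the spread between libraries, with a median residual SD of 0.0468 on 8 residual degrees of freedom. Regularized log values are shrunk towards each gene's mean, so differences, and the folds computed from them, are smaller than those of counts for genes with few reads. The spread between libraries is shrunk as well, so SDs and SEs of such genes understate the noise of their counts.

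Genes with a mean value of at least 3 over the 12 libraries, or 8 normalized counts, were tested, 15524 in all, of which 15517 had a symbol. Limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all libraries, with moderated variances that follow the mean (eBayes with a trend), for each compound against vehicle and for each pair of compounds. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and genes with an adjusted p under 0.05 were called. Error is the standard error of the difference, intervals are 95%, and group values carry the SD over 3 libraries. Lists of genes, 36 of them, were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the lists of each comparison; 35 had at least 5 measured members. Members were counted over all genes tested and adjusted over the list alone, and a single count stands where both were the same for a list that passed. Camera was repeated with a correlation estimated from the data. Limma tests each gene on its own, with a variance moderated across genes, and camera tests a list against the other genes.

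The groups, the tests, the threshold, the gene lists, the rule for naming genes and most of the other settings tried were chosen before the data were examined. The rule named, for each compound against vehicle, the 8 largest rises and 8 largest falls among called genes with a proper symbol whose treated and vehicle libraries did not overlap, a state that chance gives to 10% of genes with 3 libraries against 3. It also named up to 4 called members of each list with the largest absolute difference, a fixed set of genes, and for each pair of compounds the 6 largest differences in each direction. Genes singled out outside the rule are marked in the text as chosen after their values were seen. Coordinates are from GENCODE 29 on GRCh38.

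Responses were compared by counts of shared calls, Pearson's r and covariance across genes, beside 50 simulations without any effect. In these all 12 libraries were drawn anew, and the comparisons shared the drawn vehicle group. The test was checked on simulated data in which changes were added to genes of unchanged groups: a difference of 0.2 was called for 65.7% to 82.1% of genes over the 6 comparisons, and a difference of 0.5 for 98.5% to 100%, with 3.26% to 6.45% of calls false. A cholesterol list shifted by -0.3 was called in all 6 comparisons, with 0 of the other lists called. Simulated genes were drawn independently, and the other added changes lay outside all lists. The check therefore cannot show how often lists of correlated genes are called falsely.

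The other settings fixed then were no filter and a filter at a mean of 5, median-centred and quantile-normalized libraries, only the 2 groups compared, a robust variance estimate, no mean-variance trend, library weights, an added size of at least 1 on the log2 scale, the replicate number as a block, fry in place of camera, camera with an estimated correlation and leaving out each library in turn. Settings added after seeing the data were removal of each library's trend on GC content and length (values for 15095 genes, 97.2% of those tested), leaving out both libraries farthest from their groups, and the library's level of 17 nuclear-retained transcripts as a covariate. These 17 include NEAT1, MALAT1 and mRNAs such as DDX5 and SRSF5. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.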

Results

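The data were gene expression values from U87, a human glioblastoma cell line also known as U87MG, treated with vehicle or with 1 of 3 compounds that the labels number 1, 4 and 5. Compound 1 was given at 30 µM, compound 4 at 10 µM and compound 5 at 5 µM, and cells were harvested after 72 h. The series title names taxodione, a plant diterpene, and paclitaxel, a microtubule-stabilizing drug, but the labels do not say which number stands for which molecule, so the compounds are named by number. Each of the 4 groups held 3 libraries of poly(A) RNA, which the labels call independent biological replicates. Values were regularized log (rlog) values on the log2 scale, and 15524 genes with a mean of at least 3 were tested. No read counts were given, so the depth of each library is unknown. The rlog step pulls each gene's values towards its mean, most strongly for genes with few reads, so the differences below understate changes of weakly expressed genes. It also narrows the spread between libraries, from which SDs, SEs and p-values come. The median residual SD was 0.028 for genes with a mean of 3 to 5, against 0.052 for a mean of 8 to 11.

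Libraries of each group lay together. The first principal component held 59.3% of the variance and separated compounds 4 and 5 from vehicle and compound 1, and the second held 16.2%. The root mean square difference between libraries of the same group was 0.0606 to 0.0996 on the log2 scale, against 0.0922 to 0.218 between libraries of different groups. Replicate 1 of compound 5 stood apart from its group on the fourth component, with a score of 7.45 against -2.91 and -3.52. Markers of neurons, leukocytes, epithelium and endothelium, checked for RNA of other cells, passed the list test in none of the 6 comparisons (camera with Benjamini-Hochberg adjustment, preset correlation of 0.01). Of these markers, 6 of 14 for neurons, 10 of 15 for leukocytes, 8 of 14 for epithelium and 6 of 12 for endothelium had a mean rlog below 3. Of the 5 leukocyte markers measured, 3 rose with compound 4 and 2 with compound 5, and 0 fell with either (camera adjusted p = 0.159 and 0.274). Fry, which tests a list on its own, called leukocyte markers higher with compounds 4 and 5 against vehicle (adjusted p = 4.51e-04 and 0.00756) and against compound 1 (0.00153 and 0.0319). It called neuron markers higher with compound 5 against vehicle (0.00650) and compound 1 (0.00832), and endothelial markers lower with compound 5 against compound 1 (0.0266).

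**Figure D1:**
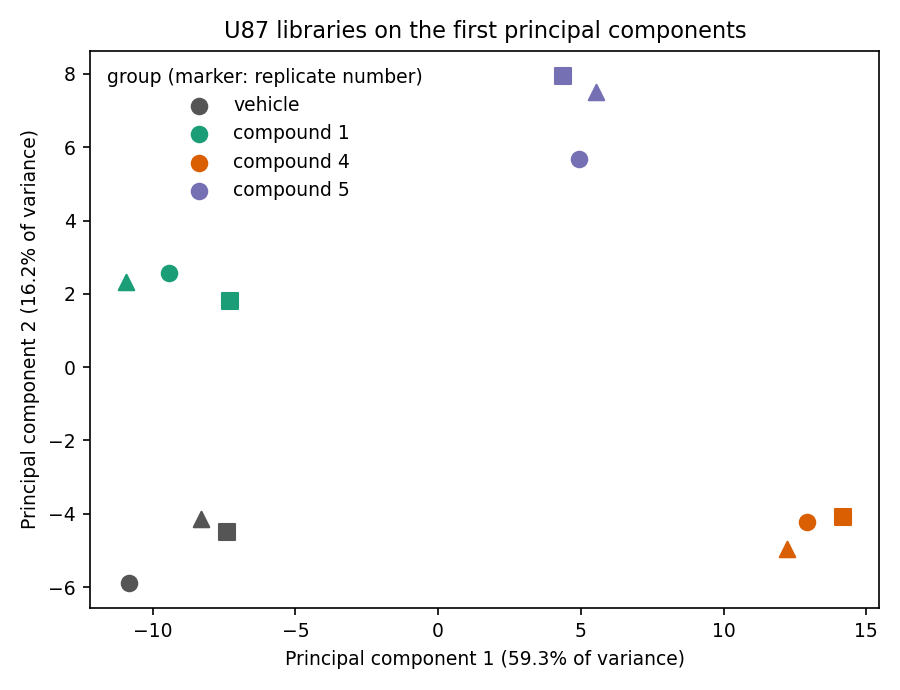
Scores of the 12 U87 libraries on the first and second principal components of 15524 genes, which held 59.3% and 16.2% of the variance. Each point is 1 library, coloured by group, with the marker shape giving the replicate number, and the libraries of each group lie together.

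Compound 4 was compared with vehicle to find which transcripts changed after 72 h at 10 µM. Genes of sterol and fatty acid synthesis fell most. HMGCS1, the cytosolic HMG-CoA synthase of the mevalonate pathway (ENSG00000112972.15, GRCh38 chromosome 5, 43289395 to 43313512), fell by 2.30 on the log2 scale (SE 0.072, n = 3 per group), from 12.45 ± 0.10 (SD, n = 3) to 10.15 ± 0.17 (limma, Benjamini-Hochberg adjusted p = 1.45e-19). SCD, the stearoyl-CoA desaturase (ENSG00000099194.6, chromosome 10, 100347124 to 100364834), fell by 2.12 (SE 0.067), from 16.99 ± 0.11 to 14.87 ± 0.12. In the list of cholesterol biosynthesis genes, 24 of 25 measured members fell and 0 rose, with 24 falls adjusted over the list alone and a median of -0.92. MSMO1 (-1.86), DHCR7 (-1.53), IDI1 (-1.44) and SQLE (-1.30) were among them. PMVK, at -0.037 and chosen after its value was seen, did not pass. The list passed camera (Benjamini-Hochberg adjusted p = 6.27e-33, or adjusted p = 0.0678 with an estimated correlation). Of 17 genes of fatty acid synthesis and desaturation, 14 fell and 2 rose, the same counts as adjusted over the list alone. FASN (-1.78), FADS2 (-1.53) and ACSS2 (-1.03) followed SCD (list: camera adjusted p = 2.90e-12, or adjusted p = 0.0712 with an estimated correlation).

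Secreted inflammatory factors rose with compound 4. IL1B, which encodes the cytokine interleukin 1 beta (ENSG00000125538.12, chromosome 2, 112829751 to 112836903), rose by 2.53 (SE 0.082, 5.78-fold on the rlog scale, limma adjusted p = 3.22e-19), from 12.91 ± 0.15 to 15.44 ± 0.090 (SD, n = 3). Other rises were IL11 at 2.11, CSF3 at 1.80, the neutrophil chemokine CXCL8 at 1.70 and IL6 at 1.33. In the list of NF-kB targets and secreted inflammatory factors, 21 of 28 measured members rose and 2 fell, against 22 and 2 adjusted over the list alone. The list median was 0.69 (camera adjusted p = 1.23e-17, or adjusted p = 0.0712 with an estimated correlation). SERPINB2, a plasminogen activator inhibitor, rose by 1.95 and the cytokine gene LIF by 1.61. CXCL1, CXCL2 and CXCL3 are close paralogs, and how reads were divided between them is not given in the sources used here.

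HSPA6, an inducible HSP70 chaperone (ENSG00000173110.8, chromosome 1, 161524540 to 161526910), had the largest rise with compound 4 among the genes tested that have a gene symbol, at 2.67 (SE 0.070, 6.38-fold, limma Benjamini-Hochberg adjusted p = 3.31e-21), from 6.91 ± 0.078 to 9.58 ± 0.22 (SD, n = 3). Of 23 heat shock genes, 12 rose and 3 fell, also when adjusted over the list alone (median 0.095, camera adjusted p = 0.00170, or adjusted p = 0.252 with an estimated correlation). CRYAB rose by 0.98, HSPA1B by 0.87 and DNAJB1 by 0.43, whereas SERPINH1, a collagen chaperone, fell by 0.76. HSPA1A rose by 0.63, but it and HSPA1B are near-identical copies and their separate values are uncertain. HMOX1, the heme oxygenase gene (ENSG00000100292.18, chromosome 22, 35380361 to 35394214), rose by 1.52 (SE 0.039) and the ferritin gene FTH1 by 0.75. The NRF2 target list that holds both did not pass as a list, with 8 of 23 members higher and 9 lower (camera adjusted p = 0.915). Its members TXNRD1 (0.058) and SRXN1 (0.034) did not pass. Metallothionein and zinc export genes rose in 6 of 7 cases and fell in 1, with MT2A at 0.71 and MT1E at 0.66 (camera adjusted p = 3.53e-05, or adjusted p = 0.0712 with an estimated correlation). The MT1 genes are close paralogs.

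Genes of DNA replication rose with compound 4 in 30 of 42 cases with 0 falls, and in 32 adjusted over the list alone (median 0.17, camera adjusted p = 1.83e-09, or adjusted p = 0.324 with an estimated correlation). CDC6 rose by 0.53, MCM10 by 0.51, the cyclin gene CCNE1 by 0.51 and RRM2 by 0.36. Of 25 genes of homologous recombination and Fanconi repair, 15 rose and 0 fell, with XRCC2 at 0.55 and BRCA1 at 0.39 (camera adjusted p = 6.49e-05, or adjusted p = 0.267 with an estimated correlation). The list of G2 and mitosis genes did not pass (4 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.915), with 4 of 36 members higher and 7 lower. Among fixed genes, MKI67 (-0.065, 95% interval -0.19 to 0.057), TOP2A (0.013) and CCNB1 (0.011) did not pass. Ribosome biogenesis genes rose in 23 of 32 cases and fell in 1, led by NOP56 at 0.73 (camera adjusted p = 6.40e-07, or adjusted p = 0.0910 with an estimated correlation). Among 27 p53 targets, 15 rose and 3 fell (camera adjusted p = 0.00170, or adjusted p = 0.174 with an estimated correlation), with GDF15 at 0.71 and GADD45A at 0.60. CDKN1A, the p21 gene, was at -0.049 and did not pass. Collagen and matrix genes fell in 18 of 33 cases and rose in 2, against 21 and 3 adjusted over the list alone, with SPARC at -0.76 and COL1A2 at -0.67 (camera adjusted p = 3.53e-05, or adjusted p = 0.252 with an estimated correlation). Of 33 tubulin and microtubule genes, 4 rose and 11 fell, including TUBA1A at -0.39 and MAP4 at -0.33. That list did not pass (camera adjusted p = 0.312), though fry called it lower (adjusted p = 0.00496).

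Immediate early and AP-1 genes also passed with compound 4: 17 of 29 rose and 9 fell, with ATF3 at 0.89, DUSP1 at 0.73 and EGR1 at -0.62 (camera adjusted p = 0.00190, or adjusted p = 0.218 with an estimated correlation). Among apoptosis regulators 13 of 31 rose and 1 fell, including the survival gene MCL1 at 0.37 and the proapoptotic gene PMAIP1 at 0.25 (camera adjusted p = 0.00282, or adjusted p = 0.0712 with an estimated correlation). Of the replication-dependent histone genes, which mostly lack poly(A) tails, 6 of 16 rose and 0 fell (camera adjusted p = 0.00666, or adjusted p = 0.0712 with an estimated correlation). Iron handling genes, which share HMOX1 and FTH1 with the NRF2 list, had 9 of 20 members higher and 6 lower (camera adjusted p = 0.0352, or adjusted p = 0.186 with an estimated correlation). That call was lost without replicate 2 of vehicle (0.0700). The ATF4 list did not pass, with 8 of 29 members higher and 13 lower (camera adjusted p = 0.328). Those higher included ATF3 at 0.89, which the AP-1 list also holds, DDIT3 at 0.38 and TRIB3 at 0.23. Among those lower was the serine synthesis gene PHGDH at -0.63. The hypoxia and glycolysis list did not pass either, with 9 of 33 higher and 11 lower (10 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.973).

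All 13 mitochondrially encoded mRNAs rose with compound 4, with a median of 0.39 and MT-CYB at 0.60 (SE 0.078, camera adjusted p = 6.40e-07 for the list, or adjusted p = 0.290 with an estimated correlation). Replicate 3 lay lower than the other compound 4 libraries, with a list median 0.17 above the vehicle mean against 0.46 and 0.49. Nuclear noncoding transcripts, read as a sign of RNA quality, moved in the same direction: 4 of 8 rose and 1 fell, with NEAT1 at 0.84 and a median of 0.10 (camera adjusted p = 0.0370, or adjusted p = 0.324 with an estimated correlation). That list no longer passed without replicate 2 of vehicle (adjusted p = 0.0606), without replicate 3 of compound 4 (0.0864) or with a filter at a mean of 5 (0.0767). With the level of 17 nuclear-retained transcripts as a covariate, the median of the mitochondrial mRNAs was 0.20 (camera adjusted p = 0.00590), while the nuclear noncoding list was not judged by this covariate, since NEAT1 and MALAT1 are part of it.

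In total 6300 of 15524 genes (40.6%) differed between compound 4 and vehicle, 2952 higher and 3348 lower (limma, Benjamini-Hochberg adjusted p under 0.05), but most differences were small, with a median absolute size of 0.18 among them. A difference of at least 1 on the log2 scale was reached by 25 higher and 17 lower genes. With each library's level of 17 nuclear-retained transcripts as a covariate, a setting chosen after seeing the data, 4071 genes passed. Of the 149 named genes called for compound 4, 134 kept their call with it.

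Compound 5 was compared with vehicle at 5 µM. IGFBP1, a secreted binding protein of insulin-like growth factors (ENSG00000146678.10, chromosome 7, 45888357 to 45893668), rose by 1.32 (SE 0.10, 2.49-fold on the rlog scale, n = 3 per group), from 8.70 ± 0.13 to 10.01 ± 0.22 (SD; limma, Benjamini-Hochberg adjusted p = 7.86e-11). HMOX1 rose by 1.25 (SE 0.039), and among inflammatory factors IL11 rose by 1.26, IL1B by 1.21, CXCL8 by 1.11 and CSF2 by 1.11. HMGCS1 fell by 1.301 (SE 0.072), FASN, the fatty acid synthase, by 1.24 and SCD by 1.17. Cholesterol biosynthesis genes fell in 23 of 25 cases with 0 rises, and 23 fell adjusted over the list alone (median -0.61, camera adjusted p = 3.29e-26, or adjusted p = 0.0779 with an estimated correlation). Of the 17 fatty acid genes, 14 fell and 1 rose (camera adjusted p = 2.63e-12, or adjusted p = 0.0779 with an estimated correlation). The inflammatory list had 22 of 28 members higher and 4 lower, the same counts adjusted over the list alone (median 0.39, camera adjusted p = 1.09e-12, or adjusted p = 0.156 with an estimated correlation).

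Genes of the ATF4 amino acid response fell with compound 5, in 23 of 29 cases with 1 rise, unchanged adjusted over the list alone (median -0.27, camera adjusted p = 4.35e-13, or adjusted p = 0.0779 with an estimated correlation). They included the amino acid transporter gene SLC7A5 at -0.57, SESN2 at -0.49, AARS1 at -0.48, CHAC1 at -0.47 and TRIB3 at -0.42. ATF3 (0.038) and DDIT3 (-0.055) did not pass. Hypoxia and glycolysis genes rose in 24 of 33 cases and fell in 1, with the glucose transporter gene SLC2A1 at 0.73, ADM at 0.71 and BNIP3 at 0.53 (median 0.23, 24 higher and 2 lower adjusted over the list alone, camera adjusted p = 3.01e-11, or adjusted p = 0.280 with an estimated correlation). DNA replication genes rose in 34 of 42 cases with 0 falls, and in 36 adjusted over the list alone, with MCM10 at 0.59 and CLSPN at 0.53 (camera adjusted p = 5.05e-15, or adjusted p = 0.262 with an estimated correlation). In the G2 and mitosis list, 7 of 36 members rose and 10 fell, and the list did not pass (7 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.365). Among NRF2 targets, HMOX1 and FTH1 (0.62) rose while AKR1C1 (-0.59), TXNRD1 (-0.38) and SLC7A11 (-0.24) fell. The list of 23 did not pass, with 4 higher and 12 lower (camera adjusted p = 0.0599). AKR1C1, AKR1C2 and AKR1C3 are close paralogs. Heat shock genes did not pass as a list (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.998), with 2 of 23 higher and 2 lower. HSPA6, named for its rise with compound 4, stood 0.21 above vehicle (SE 0.070, limma adjusted p = 0.0232).

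Matrix and invasion genes moved both ways with compound 5. TIMP3 rose by 0.75 and LOX, a collagen crosslinking enzyme, by 0.54, while THBS2 fell by 0.60 and the transcription factor gene TWIST1 by 0.62. Collagen and matrix genes rose in 14 of 33 cases and fell in 5 (median 0.069, camera adjusted p = 0.00484, or adjusted p = 0.435 with an estimated correlation). The call was lost when libraries were quantile-normalized (adjusted p = 0.0918). Mesenchymal and invasion genes rose in 14 of 31 cases and fell in 5 (16 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00158, or adjusted p = 0.156 with an estimated correlation). All 13 mitochondrially encoded mRNAs rose, with a median of 0.57 and MT-CYB at 0.71 (camera adjusted p = 4.73e-14, or adjusted p = 0.176 with an estimated correlation). With the level of 17 nuclear-retained transcripts as a covariate their median was 0.34 (camera adjusted p = 1.64e-07). Beside them, 3 of 8 nuclear noncoding transcripts rose and 1 fell, with NEAT1 at 0.72 and a median of 0.14, and that list did not pass (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0672).

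Other lists that passed with compound 5 were homologous recombination and Fanconi repair, in which 11 of 25 rose and 0 fell (13 higher and 0 lower adjusted over the list alone, camera adjusted p = 2.83e-06, or adjusted p = 0.222 with an estimated correlation), and metallothioneins and zinc export, in which 5 of 7 rose and 1 fell, with MT1E at 0.78, MT2A at 0.62 and the zinc exporter gene SLC30A1 at -0.33 (camera adjusted p = 1.48e-04, or adjusted p = 0.119 with an estimated correlation). Among YAP and TGF-beta targets 13 of 31 rose and 7 fell, with F3 at 0.93, CCN1 at 0.62 and TPM1 at 0.48 (14 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.00877, or adjusted p = 0.176 with an estimated correlation). The p53 list did not pass, with 6 of 27 members higher and 4 lower (7 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.297).

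Compound 5 changed 5443 of 15524 genes (35.1%), 2465 higher and 2978 lower (limma, Benjamini-Hochberg), of which 6 rose and 3 fell by at least 1. With the nuclear-retained transcript level as a covariate 2002 genes passed, and 109 of the 150 named genes called for compound 5 kept their call. With fry in place of camera 24 of 35 lists passed in place of 12.

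Compound 1 was compared with vehicle at 30 µM, the highest dose of the 3. IGFBP3, which encodes the main serum binding protein of insulin-like growth factors (ENSG00000146674.16, chromosome 7, 45912245 to 45921874), rose by 1.09 (SE 0.079, 2.13-fold on the rlog scale, n = 3 per group), from 13.71 ± 0.076 to 14.80 ± 0.21 (SD; limma, Benjamini-Hochberg adjusted p = 8.77e-10). It was the 1 gene that passed with a difference of at least 1. TIMP3, an inhibitor of matrix metalloproteinases, rose by 0.79 (SE 0.059), the proteoglycan gene HSPG2 by 0.60, TGFBI by 0.56, LOXL2 by 0.55 and COL5A1 by 0.50. Collagen and matrix genes rose in 13 of 33 cases and fell in 1, against 18 and 2 adjusted over the list alone (median 0.11, camera adjusted p = 8.00e-14, or adjusted p = 0.0922 with an estimated correlation). Hypoxia and glycolysis genes rose in 19 of 33 cases and fell in 1, with LOX at 0.54, ADM at 0.42, BNIP3 at 0.40, ENO2 at 0.37 and VEGFA at 0.33 (camera adjusted p = 2.02e-14, or adjusted p = 0.254 with an estimated correlation). The largest falls were CSF3 at -0.58, the nuclear receptor gene NR4A1 at -0.50 and AKR1C1 at -0.49.

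Chaperone, proteasome and cell cycle genes were lower with compound 1 by small amounts. Heat shock genes fell in 17 of 23 cases with 0 rises, and in 19 adjusted over the list alone, with HSPA8 at -0.35, HSPH1 at -0.33 and STIP1 at -0.27 (median -0.17, camera adjusted p = 7.20e-15, or adjusted p = 0.0681 with an estimated correlation). Proteasome subunit genes fell in 21 of 31 cases with 0 rises, and in 25 adjusted over the list alone, with PSMA3 at -0.20 (median -0.16, camera adjusted p = 5.02e-16, or adjusted p = 0.0922 with an estimated correlation). Of 36 G2 and mitosis genes, 17 fell and 0 rose, including CDC20 at -0.29, PLK1 at -0.26 and CCNB1 at -0.21 (0 higher and 20 lower adjusted over the list alone, camera adjusted p = 7.74e-14, or adjusted p = 0.158 with an estimated correlation). DNA replication genes fell in 11 of 42 cases, or 20 adjusted over the list alone, with CDC45 at -0.23 (camera adjusted p = 2.58e-07, or adjusted p = 0.483 with an estimated correlation). Cholesterol biosynthesis genes fell in 12 of 25 cases with 0 rises and a median of -0.12, with FDFT1 at -0.30 (0 higher and 15 lower adjusted over the list alone, camera adjusted p = 4.05e-09, or adjusted p = 0.204 with an estimated correlation). HMGCS1 (-0.073, 95% interval -0.22 to 0.075) and SCD (-0.039) did not pass. NRF2 targets fell in 10 of 23 cases, with NQO1 at -0.16 (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 7.06e-06, or adjusted p = 0.0922 with an estimated correlation). HMOX1, at -0.012, did not pass. In the inflammatory list 1 of 28 members rose and 4 fell, and it did not pass (3 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.414).

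Further lists passed with compound 1 on small medians. Nuclear OXPHOS subunit genes fell in 12 of 42 cases with 0 rises, or 19 adjusted over the list alone, with a median of -0.081 (camera adjusted p = 8.13e-08, or adjusted p = 0.320 with an estimated correlation). Mesenchymal and invasion genes rose in 8 of 31 cases and fell in 2, with TIMP1 at 0.33 and LGALS3 at 0.29 (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 9.14e-05, or adjusted p = 0.0922 with an estimated correlation). Among YAP and TGF-beta targets 6 of 31 rose and 1 fell, with the tissue factor gene F3 at 0.50 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00167, or adjusted p = 0.131 with an estimated correlation). Fatty acid genes fell in 7 of 17 cases and rose in 1, with FADS1 at -0.23 (1 higher and 8 lower adjusted over the list alone, camera adjusted p = 4.71e-04, or adjusted p = 0.303 with an estimated correlation). The ATF4 list, with 3 of 29 higher, 1 lower and STC2 at 0.33, passed (camera adjusted p = 0.0134, or adjusted p = 0.472 with an estimated correlation) but not without replicate 3 of vehicle (0.0605) or replicate 3 of compound 1 (0.0972). Iron handling genes, 1 of 20 higher and 2 lower, passed (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0183, or adjusted p = 0.158 with an estimated correlation) but not without replicate 1 of vehicle (0.0844) or with the level of 17 nuclear-retained transcripts as a covariate (0.0711, median -0.041 against -0.057). Cytosolic ribosomal protein genes, 5 of 50 lower, passed (camera adjusted p = 0.00377, or adjusted p = 0.734 with an estimated correlation) but not without replicate 3 of compound 1 (0.0844), with that covariate (0.0711, median -0.026 against -0.033) or by fry (0.314).

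Mitochondrially encoded mRNAs passed as a list with compound 1, with 3 of 13 members higher, 0 lower and a median of 0.14 (4 higher and 0 lower adjusted over the list alone, camera adjusted p = 2.56e-05, or adjusted p = 0.460 with an estimated correlation). Nuclear noncoding transcripts moved with them, 2 of 8 rising, NEAT1 by 0.54 (SE 0.075), with a median of 0.090 (camera adjusted p = 0.00728, or adjusted p = 0.320 with an estimated correlation). When the level of 17 nuclear-retained transcripts was a covariate, 5 of the 17 list calls for compound 1 ended. The median of mitochondrial mRNAs was then -0.038 (adjusted p = 0.791) and that of DNA replication genes -0.032 against -0.10 (adjusted p = 0.0711). Those of iron handling and cytosolic ribosomal protein genes are given above. The fifth was the nuclear noncoding list, of which this says nothing, since its members NEAT1 and MALAT1 are part of the covariate. Fry, which tests a list on its own, did not call mitochondrial mRNAs (adjusted p = 0.244), nuclear noncoding transcripts (0.105), DNA replication (0.164), the ATF4 list (0.0915) or ribosomal proteins (0.314). PLK1 (-0.16 against -0.26), CCNB1 (-0.17 against -0.21), CDC45 (-0.18 against -0.23) and NQO1 (-0.15 against -0.16) were no longer called with that covariate, and 48 of the 113 named genes called for compound 1 kept their call. As the covariate differs between groups it can widen SEs, so a lost call alone does not show a smaller difference. Of the 113, 84 kept their call without replicate 2 of vehicle, 88 without replicate 3 of compound 1 and 77 with no filter on low values.

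Compound 1 changed 1688 of 15524 genes (10.9%), 814 higher and 874 lower (limma, Benjamini-Hochberg). This count depended on single libraries. It was 1056 without replicate 1 of vehicle, 849 without replicate 2 of vehicle, 1043 without replicate 1 of compound 1 and 978 without replicate 3 of compound 1. It was 800 with no filter on low values, 2734 with library weights and 341 with the nuclear-retained transcript level as a covariate. With that covariate 73.0% of the genes were higher, against 48.2% without it.

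**Figure D2:**
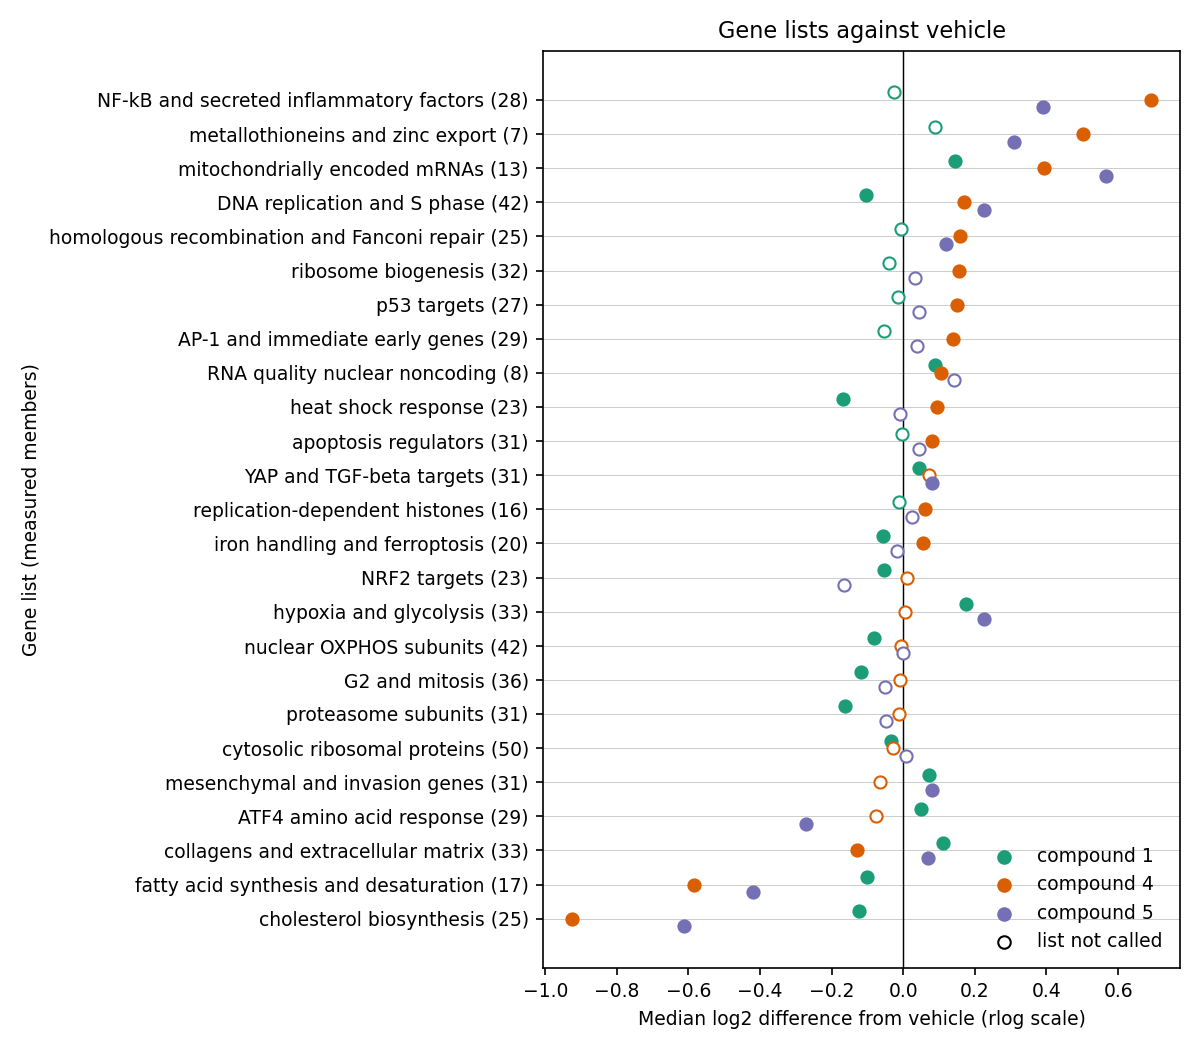
Median log2 difference from vehicle (x axis, rlog scale) over the measured members of gene lists (y axis, with the number measured), for compound 1 at 30 µM, compound 4 at 10 µM and compound 5 at 5 µM. Only lists that passed camera with at least 1 compound against vehicle are drawn. Filled points passed camera with a preset correlation and open points did not; cholesterol biosynthesis lies at -0.12, -0.92 and -0.61 for compounds 1, 4 and 5.

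**Figure D3:**
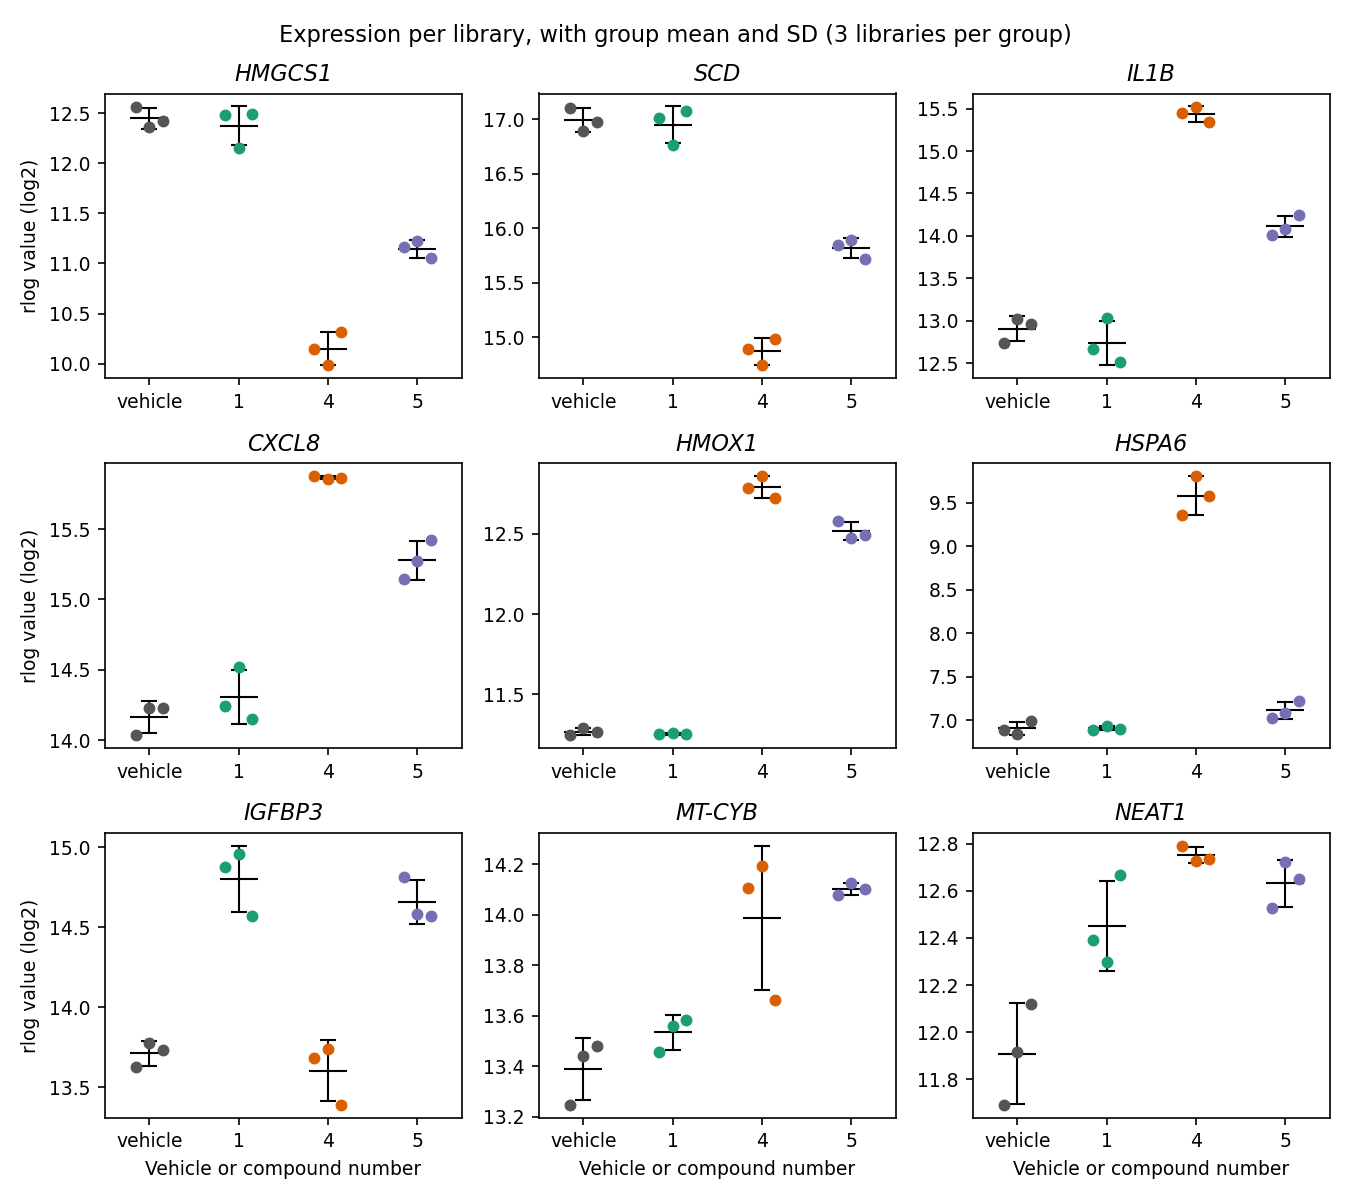
The rlog values (y axis, log2) of 9 genes in each library of the vehicle and compound groups (x axis), with horizontal lines at group means and error bars of 1 SD over 3 libraries; y axes do not start at 0. HMGCS1 and SCD were lower and IL1B, CXCL8 and HMOX1 higher with compounds 4 and 5 than in any vehicle library, HSPA6 was highest with compound 4, and IGFBP3 was higher with compounds 1 and 5.

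Responses to compounds 4 and 5 were compared with each other and with that to compound 1, at different doses. Cholesterol genes, cytokines and HMOX1 moved the same way with compounds 4 and 5. Among 15524 genes, 1565 were higher and 2052 lower than vehicle with both, against 469 and 642 for independent lists, and 112 were called in opposite directions against 1098. Log2 differences of compounds 4 and 5 correlated across genes with Pearson's r = 0.757, and genes are not independent replicates. In 50 simulations without any effect, with all libraries drawn anew and a shared vehicle group, r was 0.502 on average with 0 shared calls. Without effects the shared vehicle group alone sets that r, so it is no chance level for groups with effects. The covariance of compounds 4 and 5 was 0.0201 against 0.000933 in the simulations. Among genes called with both, the slope of compound 5 on compound 4 was 0.696.

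Compounds 1 and 5 shared 461 higher genes, IGFBP3, TIMP3 and LOX among them, and 455 lower genes, against 129 and 168 for independent lists, with 79 opposite calls against 295. Their r was 0.444 against 0.5005 in the simulations, and their covariance 0.00553 against 0.000930. Compounds 1 and 4 shared 291 higher and 313 lower genes, against 155 and 188, and had 321 opposite calls against 342, among them CSF3 and HSPA1B, lower with compound 1 and higher with compound 4. Their r was 0.154 against 0.501, or 0.0841 without replicate 1 of vehicle and 0.0746 without replicate 2 of compound 1, and their covariance 0.00237 against 0.000932. All 3 comparisons use the same 3 vehicle libraries, which cannot be split into 2 sets of at least 2. The part of the shared calls that the shared controls give was therefore not measured. The simulations hold no effects, so they cannot give that part, and an r below theirs does not mean agreement below chance. Same-direction calls of compounds 1 and 4 (604) and of compounds 1 and 5 (916) were 308 and 505 without replicate 1 of vehicle, 358 and 536 without replicate 2 of vehicle, and 395 and 596 without replicate 1 of compound 1. With no filter they were 279 and 442, with library weights 1000 and 1396, and with the nuclear-retained transcript level as a covariate 115 and 196, against 1483 for compounds 4 and 5 in place of 3617.

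**Figure D4:**
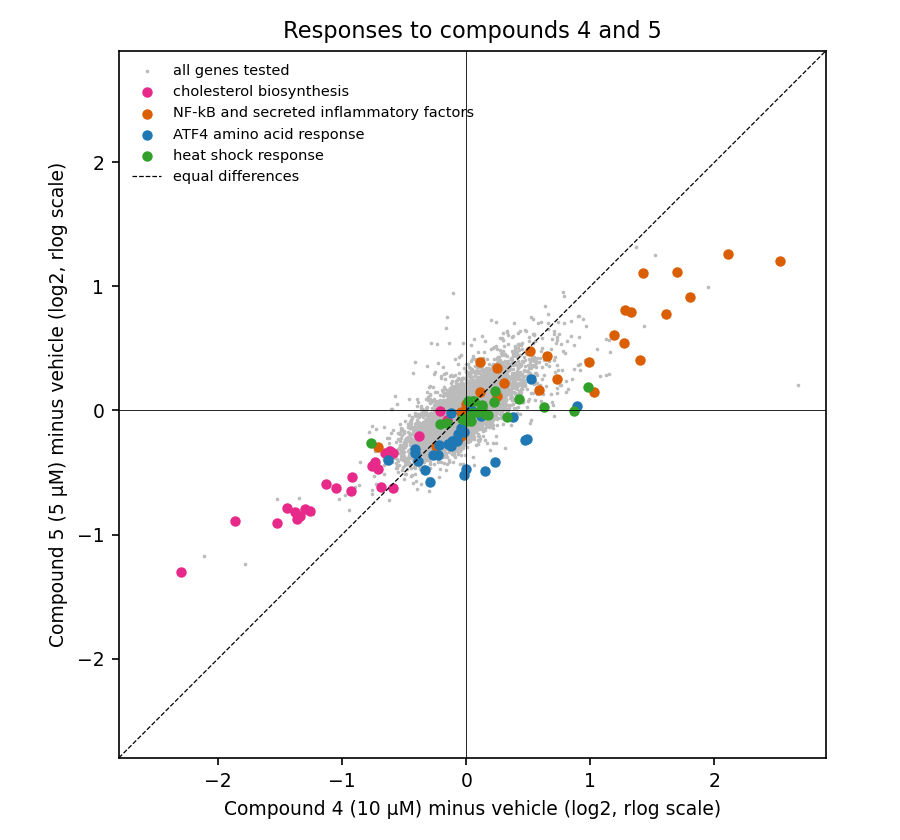
Log2 differences from vehicle on the rlog scale with compound 4 at 10 µM (x axis) and compound 5 at 5 µM (y axis) for 15524 genes, 1 point each, with the members of 4 gene lists coloured and a dashed line of equal differences. Most cholesterol genes and inflammatory factors differ more from vehicle with compound 4 than with compound 5, and genes of the ATF4 response lie mostly below 0 for compound 5.

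Compounds 4 and 5 were then compared directly, at 10 and 5 µM, so compound and dose differ together. HSPA6 was lower with compound 5 by the widest margin, at -2.47 (SE 0.070, limma Benjamini-Hochberg adjusted p = 7.88e-20), followed by IL1B at -1.32, CXCL2 at -0.99 and SERPINB2 at -0.95. IGFBP3 was higher with compound 5 by 1.05 (SE 0.079), at 14.66 ± 0.14 against 13.61 ± 0.19 (SD, n = 3), and so were HMGCS1 by 1.00, SCD by 0.94, TIMP3 by 0.91 and LOX by 0.83. Cholesterol genes were higher with compound 5 in 22 of 25 cases with 0 lower (median 0.32, camera adjusted p = 4.84e-24, or adjusted p = 0.0664 with an estimated correlation). Collagen and matrix genes were higher in 22 of 33 cases and lower in 2 (23 higher and 3 lower adjusted over the list alone, camera adjusted p = 3.33e-16, or adjusted p = 0.0664 with an estimated correlation). The inflammatory list was lower in 19 of 28 cases and higher in 2 (median -0.37, camera adjusted p = 6.55e-14, or adjusted p = 0.111 with an estimated correlation). The ATF4 list was lower in 20 of 29 and higher in 1 (1 higher and 22 lower adjusted over the list alone, camera adjusted p = 1.39e-12, or adjusted p = 0.0664 with an estimated correlation), with ATF3 at -0.86 and TRIB3 at -0.65. The DNA replication list did not pass, with 5 of 42 higher and 1 lower (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.126). MKI67 (0.019, 95% interval -0.10 to 0.14), VEGFA (0.019, -0.078 to 0.12), TUBB3 (-0.0077, -0.076 to 0.060) and MT2A (-0.090, -0.18 to -0.0025) did not differ past the threshold. In all 3422 genes differed, 1655 higher and 1767 lower with compound 5, and 3 of them by at least 1.

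Compound 4 at 10 µM differed from compound 1 at 30 µM in 6627 genes, 3238 higher and 3389 lower with compound 4, of which 44 differed by at least 1. HSPA6 was higher by 2.67 (SE 0.070), CSF3 by 2.39 and HMOX1 by 1.54, with compound 4. HMGCS1 was lower at -2.23, SCD at -2.08 and TXNIP, a thioredoxin-binding protein gene, at -1.46 (limma, Benjamini-Hochberg adjusted p = 3.23e-17). DNA replication genes were higher in 40 of 42 cases, or 41 adjusted over the list alone (camera adjusted p = 5.10e-16, or adjusted p = 0.232 with an estimated correlation). Heat shock genes were higher in 19 of 23 (camera adjusted p = 3.83e-11, or adjusted p = 0.0598 with an estimated correlation). TOP2A (0.060, 95% interval -0.026 to 0.15) did not pass.

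Compound 5 at 5 µM differed from compound 1 at 30 µM in 4666 genes, 2158 higher and 2508 lower with compound 5, of which 9 differed by at least 1. IL11 was higher by 1.48 (SE 0.089), IL1B by 1.38 and HMOX1 by 1.26, with compound 5. HMGCS1 was lower at -1.23, TSC22D3, a glucocorticoid-induced gene, at -1.01 and UNC5B at -0.83 (limma, Benjamini-Hochberg adjusted p = 4.93e-13). All 42 DNA replication genes were higher with compound 5 (median 0.30, camera adjusted p = 3.54e-29, or adjusted p = 0.128 with an estimated correlation). In contrast, 25 of 29 ATF4 response genes were lower with 0 higher (0 higher and 26 lower adjusted over the list alone, camera adjusted p = 2.14e-20, or adjusted p = 0.0623 with an estimated correlation). VEGFA (0.061, 95% interval -0.036 to 0.16), MKI67 (-0.0072, -0.13 to 0.12) and GDF15 (-0.028, -0.15 to 0.090) did not pass. Fixed gene ABCB1, the efflux pump gene, had a mean below the filter or was absent from the values, and was not tested.

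Lists that passed with no compound against vehicle included the ER unfolded protein response, in which 2, 8 and 5 of 25 members rose and 1, 6 and 8 fell with compounds 1, 4 and 5 (camera adjusted p = 0.708, 0.996 and 0.608). In the lysosome and autophagy list 3, 10 and 6 of 34 members rose and 2, 8 and 12 fell with compounds 1, 4 and 5 (camera adjusted p = 0.983, 0.915 and 0.179). In the interferon response list 1, 0 and 4 of 29 members rose and 0, 11 and 5 fell with compounds 1, 4 and 5 (camera adjusted p = 0.860, 0.159 and 0.814). Among glial and neural stem markers 1, 1 and 1 of 14 members rose and 1, 6 and 5 fell with compounds 1, 4 and 5 (camera adjusted p = 0.414, 0.137 and 0.134). By fry, glial markers were lower with compounds 1, 4 and 5 (adjusted p = 0.0350, 4.00e-05 and 4.09e-04). It also called the interferon list lower with compound 4 (adjusted p = 0.00180) and the lysosome list lower with compound 5 (0.00688). The list of aryl hydrocarbon receptor targets had 4 measured members and was not tested.

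Across the 6 comparisons camera with the preset correlation called 17, 16 and 12 of 35 lists for compounds 1, 4 and 5 against vehicle, and 20, 19 and 16 for compound 4 against 1, 5 against 1 and 5 against 4. With a correlation estimated from the data it called 0 in each, where 8, 9, 8, 12, 10 and 11 lists had an unadjusted p under 0.05, and fry called 14, 22, 24, 24, 27 and 19. The ABC transporter list passed in none of the 6 comparisons by camera, though ABCC3 rose by 0.25 and 0.50 with compounds 4 and 5 (limma, Benjamini-Hochberg). Neither did the list of 33 tubulin and microtubule genes, in which TUBB3 was at -0.0030, 0.0064 and -0.0013. By fry, however, the tubulin and microtubule list was lower with compounds 4 and 5 against vehicle (adjusted p = 0.00496 and 0.0359).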

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

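Tests of library scaling, nuclear-retained transcripts, HSP70 paralogs and dose, and the fits with GC and length trends removed or with a covariate, were chosen only after the result was seen.

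Some genes and lists were called in opposite directions against the same vehicle libraries by 2 compounds given at different doses. Only those whose difference between the 2 compounds also passed are given. For a gene, that difference exceeds either effect against vehicle and has the same SE, so its test was almost bound to pass. Much the same holds for lists. The p-values of these differences are therefore not support apart from the comparisons with vehicle. Between compounds 1 and 4, the median difference was 0.29 for heat shock genes, with medians of -0.17 and 0.095 against vehicle (camera adjusted p = 3.83e-11, or adjusted p = 0.0598 with an estimated correlation). It was 0.27 for DNA replication genes, with medians of -0.10 and 0.17 against vehicle (camera adjusted p = 5.10e-16, or adjusted p = 0.232 with an estimated correlation). It was 0.16 for iron handling genes, with medians of -0.057 and 0.054 against vehicle (camera adjusted p = 8.00e-04, or adjusted p = 0.0598 with an estimated correlation). For collagen and matrix genes it was -0.25 for the list, with medians of 0.11 and -0.13 against vehicle (camera adjusted p = 2.90e-12, or adjusted p = 0.0598 with an estimated correlation). NQO1, a quinone reductase gene, differed by 0.38, with -0.16 and 0.21 against vehicle (limma adjusted p = 3.52e-09). IL6 differed by 1.53, with -0.20 and 1.33 against vehicle (limma adjusted p = 3.53e-18). Between compounds 1 and 5, the median difference was -0.30 for the ATF4 list, with medians of 0.049 and -0.27 against vehicle (camera adjusted p = 2.14e-20, or adjusted p = 0.0623 with an estimated correlation). It was 0.30 for DNA replication genes, with medians of -0.10 and 0.23 against vehicle (camera adjusted p = 3.54e-29, or adjusted p = 0.128 with an estimated correlation). TRIB3, a stress-induced pseudokinase gene, differed by -0.57, with 0.15 and -0.42 against vehicle (limma adjusted p = 3.22e-09). IL6 differed by 0.99, with -0.20 and 0.79 against vehicle (limma adjusted p = 4.93e-13). Between compounds 4 and 5, the median difference was 0.16 for collagen and matrix genes, with medians of -0.13 and 0.069 against vehicle (camera adjusted p = 3.33e-16, or adjusted p = 0.0664 with an estimated correlation). SLC7A11, the cystine transporter gene, differed by -0.71, with 0.47 and -0.24 against vehicle (limma adjusted p = 1.68e-11). TRIB3 differed by -0.65, with 0.23 and -0.42 against vehicle (limma adjusted p = 1.95e-10). COL1A1 differed by 0.67, with -0.32 and 0.36 against vehicle (limma adjusted p = 5.90e-11).

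Several of the calls with compound 1 in these pairs lay near the threshold and ended when 1 library was left out. IL6 with compound 1 no longer passed without replicate 2 (adjusted p = 0.0776) or 3 (0.0921) of vehicle, or without replicate 1 (0.107) or 3 (0.164) of compound 1, with differences of -0.19, -0.17, -0.17 and -0.13. TRIB3 with compound 1 no longer passed without replicate 2 (0.0747) or 3 (0.308) of vehicle, or without replicate 2 (0.120) or 3 (0.218) of compound 1, with differences of 0.17, 0.090, 0.14 and 0.12. Its difference stayed at 0.15 but its p rose past the threshold without replicates 1 (0.0660), 2 (0.0592) or 3 (0.0573) of compound 4 or without replicate 2 of compound 5 (0.0549), libraries that enter that comparison only through the variance. The ATF4 list with compound 1 no longer passed without replicate 3 of vehicle (0.0605) or of compound 1 (0.0972), and the iron list without replicate 1 of vehicle (0.0844), or with compound 4 without replicate 2 of vehicle (0.0700). With the level of 17 nuclear-retained transcripts as a covariate, the iron and DNA replication lists with compound 1 no longer passed (adjusted p = 0.0711 for both), nor did NQO1 (-0.15, adjusted p = 0.154), IL6 (-0.18, 0.2999) and TRIB3 (0.18, 0.215). Without the covariate these 3 genes stood at -0.16, -0.20 and 0.15, so their calls ended with little change in size.

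Cholesterol biosynthesis genes were lower with compounds 4 and 5, with medians of -0.92 and -0.61. After removal of GC and length trends the medians were -0.92 and -0.61, so such a trend does not account for them. Library scaling would move all genes alike, but the median of the list minus that of the other genes tested was -0.92 and -0.61, so scaling does not account for it. The median over all genes was -0.0013 and -0.00095, so these values restate the list medians and are not separate support. Across the fits that left out 1 library, the list median nearest 0 was -0.58, so no single library carried the fall. A compound effect on sterol synthesis genes may therefore be put forward as a hypothesis, at doses that differ between compounds.

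Mitochondrially encoded mRNAs were higher with all 3 compounds, and without GC and length trends the lowest of the 3 medians was 0.15, against 0.14 before, which argues against such trends as the whole cause. Within groups, the deviation of their median over 12 libraries went with that of 17 nuclear-retained transcripts (Pearson's r = 0.636, exact permutation p = 0.0301; Spearman's rho = 0.685, exact permutation p = 0.0239; both two-sided, with Benjamini-Hochberg adjusted p = 0.0301 for both). The r was 0.746 without replicate 3 of compound 4 and replicate 1 of vehicle. With that level as a covariate the medians were -0.038, 0.20 and 0.34 for compounds 1, 4 and 5, and the list still passed with compounds 4 and 5 (camera adjusted p = 0.00590 and 1.64e-07 at the preset correlation; without the covariate, adjusted p = 0.290 and 0.176 with an estimated correlation) while the call with compound 1 ended (adjusted p = 0.791). A library difference tracked by these 17 transcripts may thus account for the compound 1 pattern and part of the others. Their level is not a direct measure of nuclear RNA, since they include mRNAs such as DDX5 and SRSF5. As the covariate also differs between groups, an effect of the compounds on both the mitochondrial mRNAs and these transcripts stays open.

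HSPA6 and other heat shock genes were higher with compound 4. HSPA6 rose by 1.81 more than HSPA1B (SE 0.0864, the 2 genes taken as independent). Reads shared with HSPA1B therefore do not account for the rise of HSPA6. Other HSP70 paralogs were not compared, so sharing with them stays open. Of 18 list members outside the HSPA family, 9 rose while 3 fell, so the rise was not confined to that family. After removal of GC and length trends HSPA6 differed by 2.67 (limma adjusted p = 1.40e-21). The rise with compound 5 was 0.0769 of that with compound 4, and as compound 5 was given at 5 µM and compound 4 at 10 µM, dose and compound cannot be told apart in that contrast. A response of chaperone genes to compound 4 at 10 µM may be put forward as a hypothesis, which was not tested further. The heat shock list did not pass with an estimated correlation (camera adjusted p = 0.252).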

How the results depend on the processing

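The fits with GC and length trends removed, without both libraries farthest from their groups, and with nuclear-retained transcripts as a covariate were chosen only after the result was seen.

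Values below are counts of genes in the order compound 1, 4 and 5 against vehicle, 4 against 1, 5 against 1 and 5 against 4, which were 1688, 6300, 5443, 6627, 4666 and 3422. With a size of at least 1 on the log2 scale as well they were 1, 42, 9, 44, 9 and 3, since few differences are that large. Compound 1 had 800 genes with no filter and 2734 with library weights. Its shared calls with compounds 4 and 5 were 279 and 442 with no filter, and 1000 and 1396 with weights. The cause was not tested. With the covariate, compounds 1, 4 and 5 had 341, 4071 and 2002 genes. Shared calls were 115 (1 and 4), 196 (1 and 5) and 1483 (4 and 5); higher genes made up 73.0% of those of compound 1, against 48.2% without it. The covariate differs between groups, so it can remove part of a compound effect and can also widen its SE. A lost call alone therefore does not show that a difference became smaller. The covariate turned MALAT1 with compound 5 from 0.42 to -0.11 (limma adjusted p = 0.601) and MEG3 with compound 1 from 0.25 to -0.064 (adjusted p = 0.788). MALAT1 is 1 of the 17 transcripts of the covariate; for MEG3 the cause was not tested. Camera with an estimated correlation called 0, 0, 0, 0, 0 and 0 lists, with 8, 9, 8, 12, 10 and 11 at an unadjusted p under 0.05. Fry, which tests a list on its own, called 24 with compound 5 in place of 12. The camera runs differed only in how the correlation between genes was set. Why fry called more lists was not tested.

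Leaving out 1 library at a time, compound 1 had 849 to 2363 genes, with 1056 without replicate 1 and 849 without replicate 2 of vehicle, and 1043 without replicate 1 and 978 without replicate 3 of compound 1. Shared calls were 308 to 873 for compounds 1 and 4 and 505 to 1236 for compounds 1 and 5, with 308 and 505 without replicate 1 of vehicle, 358 and 536 without replicate 2 of vehicle, and 395 and 596 without replicate 1 of compound 1. The other counts stayed within 1.5 times, at 5128 to 6819, 4242 to 5701, 5687 to 7135, 3610 to 4882 and 2426 to 4060. With both farthest libraries out the counts were 1736, 7061, 5977, 6388, 4370 and 4415, and without GC and length trends 1909, 6362, 5512, 6743, 4668 and 3634. With the replicate block they were 1706, 6309, 5484, 6627, 4690 and 3462; residuals of same-numbered libraries correlated above 0.1 in 4 of 18 pairs (-0.22 to 0.25), and 6 of 12 libraries fitted best with their own number, so no clear pairing by number was seen, and whether such libraries shared a day is not given in the sources used here. Of 100 list calls, 100 held with the block, 99 with median centring, 98 with quantile normalization, 96 with a filter at 5, 97 without GC and length trends, 92 with the covariate and 91 with fry. Of 595 gene values, 472 kept their side of the threshold with the covariate, 541 with no filter, and 554 to 588 without any 1 library. Called values among these also kept their direction, which was not checked for values that were not called.

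Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In each comparison 1 of 10, the real one, gave as many genes (limma), with the highest of the others at 0, 0, 0, 0, 1 and 0. The other splits mix libraries of both groups, so any effect widens their spread. Their low counts therefore do not show what unrelated groups would give. Depth is unknown, and changes of 0.2 were called for 65.7% to 82.1% of simulated genes.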

Other observations

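The tests of clock genes, nuclear-retained transcripts and LXR targets were all chosen only after the result was seen. Their adjusted p values are over 38 lists, the 35 fixed before and these 3. That adjustment does not correct for a choice made on these same values.

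Of 15 measured circadian clock genes, 10 fell and 2 rose with compound 4 (median -0.18; camera adjusted p = 0.00412, or adjusted p = 0.0662 with an estimated correlation), and 6 fell and 1 rose with compound 5 (median -0.086; camera adjusted p = 0.0151, or adjusted p = 0.138 with an estimated correlation). With compound 1, 2 rose and 0 fell and the list did not pass (camera adjusted p = 0.252). PER1, a repressor of the clock, fell by 0.44 and 0.52 with compounds 4 and 5, and the output genes TEF by 0.44 and 0.34 and DBP by 0.32 and 0.23 (limma, Benjamini-Hochberg). BMAL1, which encodes an activator, rose by 0.19 with compound 4 and 0.12 with compound 5 (limma adjusted p = 0.0488 for compound 5). The larger of the 2 rises with compound 4 was that of NR1D1, at 0.24 (limma adjusted p = 3.28e-05). NR1D1 stood at 0.0055 with compound 5 and did not pass.

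SREBF2, the transcription factor gene that drives sterol synthesis genes, fell by 0.74 and 0.42 with compounds 4 and 5, and SREBF1 by 0.54 and 0.28 (limma, Benjamini-Hochberg; both chosen after their values were seen). Of 17 nuclear-retained and speckle transcripts, 9 rose and 0 fell with compound 1 (12 and 1 adjusted over the list alone, camera adjusted p = 7.72e-08, or adjusted p = 0.263 with an estimated correlation), 11 and 1 with compound 4 (camera adjusted p = 3.41e-05, or adjusted p = 0.294 with an estimated correlation), and 15 and 1 with compound 5 (16 and 1 adjusted over the list alone, camera adjusted p = 9.37e-09, or adjusted p = 0.204 with an estimated correlation). WSB1 rose by 0.54, 0.43 and 0.64 and CCNL2 by 0.46, 0.38 and 0.60 with compounds 1, 4 and 5.

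ABCA1, a cholesterol exporter gene and a target of the nuclear receptor LXR, rose by 0.19 with compound 1 and 0.56 with compound 4, and stood at 0.081 with compound 5. LXR activation was tested as a hypothesis: of 6 measured LXR targets, 2 rose and 2 fell with compound 4, with a median of -0.067 (camera, unadjusted p = 0.439). ABCA1 and MYLIP (0.12) were higher and SREBF1 and LPCAT3 (-0.32) lower. The targets moved both ways, so LXR target activation may or may not be present and the test left it open.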
